A study of Homo sapiens with 12 samples.

How the data were processed

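Transcript levels were measured in 12 cultures of MDA-MB-231, an oestrogen receptor-negative human breast cancer cell line. Per the labels, the cells were infected for 24 h with an adenovirus carrying either the full-length human oestrogen receptor alpha (Ad-ERα) or, as the control vector, LacZ (Ad-LacZ), and were then treated for 48 h with 10 nM 17β-estradiol (E2) or with 0.01% ethanol as vehicle. Each of the 4 combinations of vector and treatment has 3 arrays, which the labels call independent biological replicates. Total RNA was profiled on Affymetrix arrays, per the labels, with 22283 probe sets on each array, of which 68 are control probe sets. The virus dose, the scanner software, its version and its scaling are not given in the sources used here.

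The deposited values are intensities on a linear scale, with no value below 0. On every array the mean over all probe sets without the highest and lowest 2% lay between 500.1 and 500.2, so each array had been scaled as a whole to a common target before deposit. Median intensity per array ranged from 158.5 to 209.3. The number of arrays limits the precision. The ratio of the 3′ to the 5′ control probe set of GAPDH ranged from 0.803 to 1.04 over the 12 arrays, and that of ACTB from 0.706 to 1.40.

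The intensities were transformed as log2(value + 15.9), the added value being the 10th percentile of the whole table. A fold change is therefore on that scale and understates the change of dim probe sets. The medians of the 12 arrays ranged from 7.45 to 7.82 on the log2 scale, a spread of 0.37, which was above the tolerance of 0.2, so each array was shifted to the mean of the array medians. Probe sets were kept when the highest of the 4 group means lay above the 40th percentile (6.99 on the log2 scale, an intensity of 111), which left 14241 probe sets and, among them, 8563 genes. Probe sets were named from the platform annotation given with the series: 19065 probe sets have 1 symbol, 1043 have several and are not named here, and 2107 have no listed symbol. Of the 19065 named probe sets, 19059 matched a current RefSeq symbol and 0 symbols were updated.

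Each probe set was fitted with limma 3.58.1 in R 4.3.3 over all 12 arrays with 1 mean per group (8 residual degrees of freedom, eBayes with an intensity trend, 5.29 prior degrees of freedom). All p-values of genes are limma's, two-sided and adjusted by Benjamini-Hochberg over the 14241 probe sets, and a probe set was called at an adjusted p under 0.05. The comparisons were E2 against vehicle in Ad-ERα cells, the same in Ad-LacZ cells, the difference between those effects (the interaction), and Ad-ERα against Ad-LacZ in vehicle and in E2. Per comparison, genes were named by size of change among called probe sets whose groups did not overlap, with 1 probe set per gene, the one with the highest mean over the 12 arrays (up to 12 highest and 12 lowest for E2 in Ad-ERα cells and for the vectors in vehicle, up to 5 and 5 otherwise, with no condition on overlap for the interaction). Up to 4 members per gene list with the smallest adjusted p and a fixed set of receptor and cell cycle genes were named as well. The groups, the tests, the rule for named genes, the gene lists and the alternatives were fixed before the data were examined, except where stated.

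A total of 28 gene lists holding 702 distinct genes, 634 of them on the array, were tested with limma's camera (preset correlation of 0.01) on 1 probe set per gene, against all other genes, with Benjamini-Hochberg adjustment over the 26 lists that had at least 5 measured members. They covered oestrogen response, cell cycle, growth control, stress, metabolism, signalling and markers of cell types. A correlation estimated per list, and limma's fry, were run beside it.

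The array titles end in codes that fall into 3 sets, each with 1 array per group, and what the codes stand for is not given in the sources used here. Deviations from the group means correlated between 0.276 and 0.646 in all 18 pairs of arrays within a set, above the limit of 0.1 fixed beforehand, and between −0.445 and 0.063 in the 36 pairs across sets, and 12 of 12 arrays correlated best with an array of their own set. The sets were therefore taken to pair the arrays, and replicates 1, 2 and 3 of each group are the arrays of code sets 1, 2 and 3. Results with the code sets as a block are printed beside a result where they change a call or move a count by over 1.5 times. For members of a list, the count with the block is the one over all probe sets.

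The fits were tested on simulated data for E2 against vehicle in Ad-ERα cells, with 200 of 14241 probe sets changed by known amounts, in 100 simulations per kind of noise. With independent noise and shared effects of the code sets, the fit without a block recovered 16.9% of changes of 1, 81.1% of changes of 2 and 98.7% of changes of 4 on the log2 scale, with a median of 1 and at most 3 false calls. The fit with the block recovered 56.3%, 92.9% and 99.5%, with a median of 8.5 and at most 19 false calls. With noise made by exchanging residuals of whole arrays within code sets, which keeps the correlation between genes, the fit without a block recovered 10.4%, 77.4% and 98.4% with at most 6 false calls. The fit with the block recovered 56.1%, 94.6% and 99.8% with a median of 1 false call, but 4 of 100 simulations gave over 100 false calls, the highest number being 495. A first run of 20 simulations had given over 100 false calls with the block in 4 of the 20, the highest 1426, and was extended to a new run of 100 for that reason. With no changed probe set, the fit without a block made 0 calls in all 100 simulations, while the fit with the block made calls in 4, and 865 of them in 1 simulation. Counts with the block carry this limit. The exchanged residuals include those of the Ad-ERα E2 arrays, so an E2 effect that is unequal between code sets would remain in these simulations. In the same simulations without change, camera with its preset correlation called on average 0.64 of the 26 lists, at least 1 list in 51 of 100 simulations and at most 5, and 1.53, in 75 of 100 and at most 8 with the block. With the estimated correlation the average was 0.01 without the block and 0 with it.

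The alternatives were quantile normalization, other added values, no filter and a filter at the 60th percentile, other spread models, array weights, fits to 2 groups alone, 1 probe set per gene, the code sets or the code prefix as a block, leaving out each array and each code set, and, for the lists, the estimated correlation, fry and another choice of probe set. The deposited scaling without a shift, and the block together with the estimated correlation, were added after seeing the data. All splits of 6 arrays into 3 and 3 (10), and 100 drawn splits for the interaction, were refitted to count how often other groupings call as many probe sets or lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No array was left out.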

Results

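Gene expression was profiled in MDA-MB-231 breast cancer cells, which lack the oestrogen receptor, after the receptor had been returned to them by an adenovirus. The design crossed the vector (Ad-ERα or the control Ad-LacZ) with the treatment (10 nM E2 or vehicle), with 3 arrays in each of the 4 groups and 14241 of 22283 probe sets bright enough to be tested. The median intensity of the 12 arrays lay between 158.5 and 209.3. The series title asks how E2 slows the growth of cells that express the receptor again, by way of cell cycle genes.

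The introduced gene was read first. ESR1 encodes the receptor, and the ESR1 probe set with the highest mean log2 value over the 12 arrays rose from an intensity of 139.6 ± 55.5 (SD, n = 3) in Ad-LacZ vehicle arrays to 20803 ± 9869 (SD, n = 3) in Ad-ERα vehicle arrays, a log2 difference of 7.02 (SE 0.41) or 130-fold (limma, adjusted p = 1.38e-06). In E2 the same probe set read 121.4 ± 55.3 in Ad-LacZ and 23618 ± 7053 in Ad-ERα arrays, and its level in Ad-ERα cells differed between E2 and vehicle by less than the spread between replicates (log2 0.28, adjusted p = 0.935). Each of the 6 Ad-ERα arrays lay above each of the 6 Ad-LacZ arrays, and the lowest of them, the vehicle array of replicate 1, read 9505. A total of 5 ESR1 probe sets were called in vehicle, with log2 differences up to 8.62. Another 2 ESR1 probe sets were not called (log2 0.02 and 0.49), and 2 more lay below the level for testing. Whether these 4 probe sets lie inside the coding sequence carried by the vector is not given in the sources used here, so they check nothing.

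E2 in cells carrying the receptor raised several known oestrogen targets. TFF1, a secreted trefoil peptide and a standard marker of oestrogen action, rose from an intensity of 184.4 ± 36.0 to 4026 ± 326 (SD, n = 3 each; log2 4.34, SE 0.27, adjusted p = 3.28e-06), and its relative TFF2 rose from 220.0 ± 195.8 to 5038 ± 463 (log2 4.72, adjusted p = 0.00214). ALPP, the placental alkaline phosphatase, rose from 13.4 ± 10.3 to 1427 ± 757 (log2 5.50, SE 0.47, adjusted p = 5.55e-05). Its level in vehicle lies below the added value of 15.9, so the size of its log2 change depends on that value. SERPINA1, the secreted protease inhibitor alpha-1 antitrypsin, rose 8.35-fold to 8481 ± 1190 (log2 3.06, adjusted p = 6.69e-06), and GREB1, a cofactor of the receptor, rose by 2.40 on the log2 scale (adjusted p = 0.00522). CDH1, the epithelial adhesion protein E-cadherin, rose from 34.1 ± 15.9 to 837.1 ± 572.0 (log2 3.86, adjusted p = 0.00291). The lower end held FOSL1, a subunit of the AP-1 transcription factor, which fell from 3491 ± 515 to 1295 ± 342 (log2 −1.44, adjusted p = 0.00501), and CDC20, which activates the anaphase-promoting complex, from 1290 ± 137 to 581.7 ± 142.3 (log2 −1.16, adjusted p = 0.0316).

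In all, 161 probe sets were called, 147 higher and 14 lower with E2. Of these, 74 changed over 4-fold. They name 112 genes that rose and 14 that fell. Others at the upper end were TNNC1, a troponin subunit (log2 4.30, from an intensity of 3.73 in vehicle), the chemokine CXCL14 (4.17), OLFML3 (3.71), GJA1, the gap junction protein connexin 43 (3.70), the keratin KRT13 (3.62), INHBB, a subunit of inhibin and activin (3.50), the water channel AQP5 (3.40) and the complement component C3 (3.22). Lower genes were ROBO3 (log2 −1.62), GSDMD, which forms pores in dying cells (−1.54), FAM216A (−1.44), CEP55, needed for the last step of cell division (−1.30), SLC43A3 (−1.15), PCLAF, a partner of the replication clamp (−1.08), and GINS1, part of the replicative helicase (−1.02). The calls of ROBO3 (limma adjusted p = 0.0466), SLC43A3 and CEP55 were lost without 10, 9 and 8 of the 12 arrays in turn, and that of C3 without 6. That of GSDMD was lost without 4, of PCLAF without 3, of GJA1 and AQP5 without 2 each, and of TNNC1 without 1. Outside the rule of 1 probe set per gene, a probe set of TMOD1 was called with a log2 change of 4.30. ROBO3 read 136.7 in Ad-ERα vehicle and 34.1 in Ad-ERα E2 arrays, against 54.7 in Ad-LacZ vehicle and 88.1 in Ad-LacZ E2 arrays. With the code sets as a block 845 probe sets were called, 504 higher and 341 lower. In 1 of 100 simulations without any added change this block gave 865 calls. The count was 347 without replicate 1, 73 without replicate 2 and 56 without replicate 3 of the Ad-ERα E2 arrays. It was 101 without replicate 1 and 86 without replicate 2 of the Ad-ERα vehicle arrays, and 250, 21 and 8 without code set 1, 2 or 3.

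Of 38 named results called in this comparison, 16 kept their call whichever of the 12 arrays was left out, among them TFF1, TFF2, ALPP, SERPINA1, GREB1, CXCL14, KRT13, OLFML3, INHBB, CDH1, FOSL1 and FAM216A. The call of CDC20 was lost without replicate 2 or 3 of the Ad-ERα E2 arrays (adjusted p = 0.101 and 0.214) and without any 1 Ad-ERα vehicle array (0.0569, 0.142 and 0.101). It was also lost without replicate 3 of the Ad-LacZ E2 (0.0533) or Ad-LacZ vehicle arrays (0.0509). The call of GINS1 was lost without replicate 3 of the Ad-ERα E2 arrays (0.108) or replicate 1 or 2 of the Ad-ERα vehicle arrays (0.0615 and 0.0747). Each of the 22 named calls lost without some array was lost without replicate 2 or replicate 3 of the Ad-ERα E2 arrays. The highest adjusted p was 0.267, for MT1X without replicate 2 of the Ad-ERα E2 arrays.

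**Figure D1:**
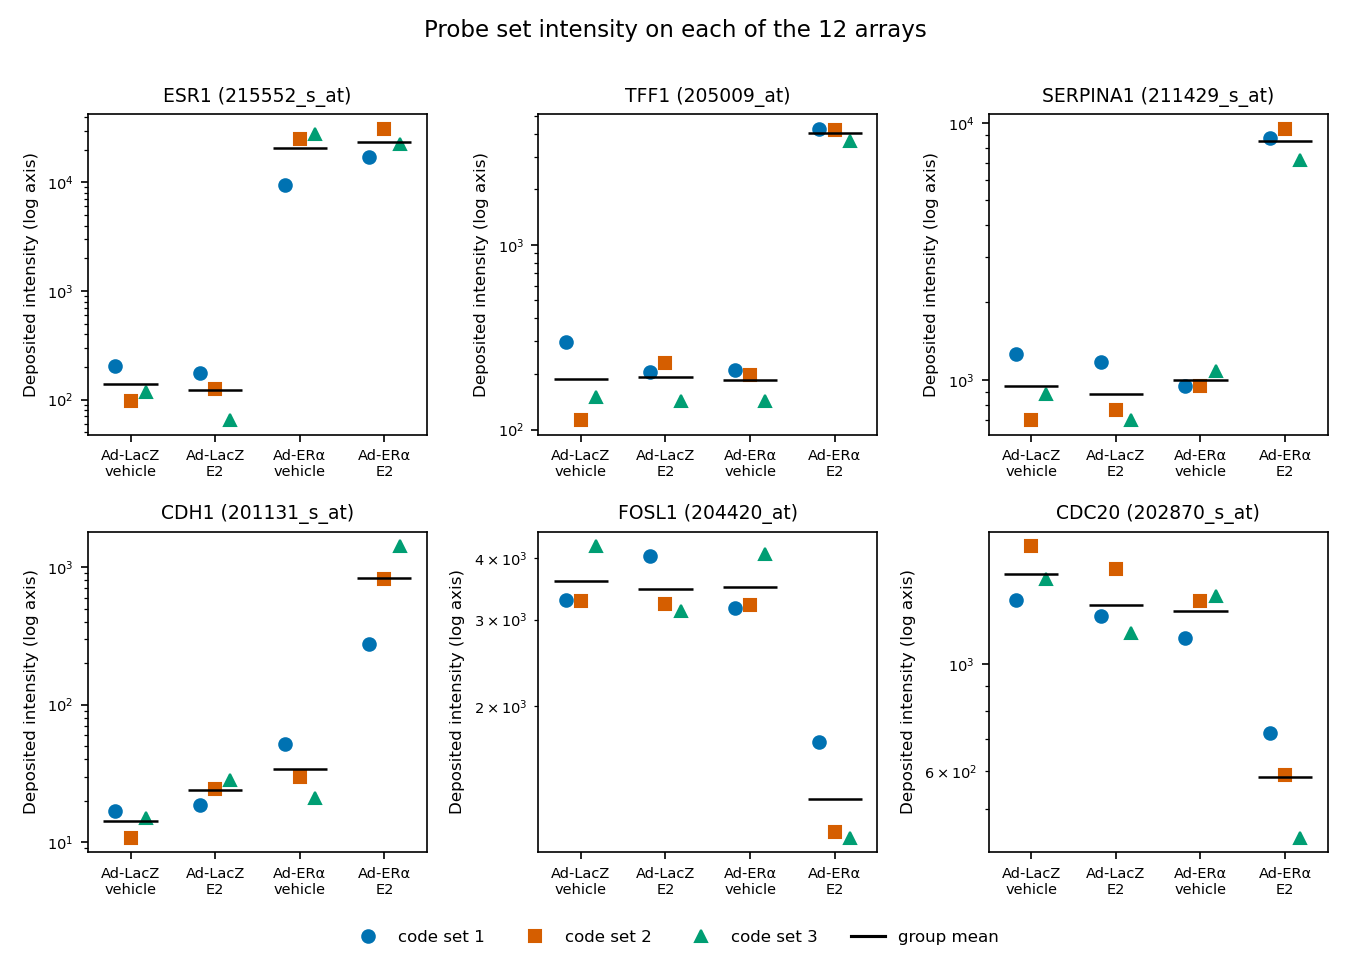
Deposited intensity (log axis) of 6 probe sets on each of the 12 arrays, with the 4 groups along the horizontal axis, a symbol and colour per code set and a line at each group mean. ESR1 is high in both Ad-ERα groups, while TFF1, SERPINA1 and CDH1 are high, and FOSL1 and CDC20 low, in the Ad-ERα arrays with E2.

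Genes of cell division were lower with E2 in Ad-ERα cells. In the list for G2/M and mitosis, 49 of 50 measured genes had a negative log2 change, with a median of −0.78 (adjusted p = 2.34e-22, camera). With an estimated correlation the adjusted p = 0.162, and with the block and an estimated correlation it was 0.0403. A single member, CDC20, passed over all probe sets, 27 members were lower when adjusted over the list alone, and 32 were lower over all probe sets with the block. CCNB1, the mitotic cyclin B1, read 1516 ± 329 in vehicle and 829.3 ± 166.7 in E2 (log2 −0.86, adjusted p = 0.161, 0.0042 with the block). The proliferation marker MKI67 had a log2 change of −0.77 (adjusted p = 0.202, 0.0108 with the block). Genes of the G1/S transition and DNA replication had a median of −0.50 over 42 members (adjusted p = 1.97e-07; adjusted p = 0.606 with an estimated correlation), with 1 member, GINS1, lower over all probe sets, 4 lower when adjusted over the list alone and 10 lower with the block.

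The other growth control lists were not called as wholes. Among CDK inhibitors, pocket proteins and growth arrest genes, 0 of 23 members passed limma's test over all probe sets by the 1 probe set used per gene. Another probe set of the growth arrest gene GADD45B was called as higher (log2 1.89), and also in the interaction (2.27, limma adjusted p = 0.0444). Adjusted over the list alone, 5 members were higher and 1 lower (list adjusted p = 0.676). The list holds 6 higher and 1 lower member with the block. CDKN1A, the CDK inhibitor p21, read 1594 ± 194 in vehicle and 3732 ± 1236 in E2 (log2 1.16, adjusted p = 0.0892, 0.0026 with the block). Of the 15 D-type cyclins, G1 kinases and MYC, 0 passed over all probe sets, 2 were lower with the block and 2 when adjusted over the list alone, with a median of −0.25 (list adjusted p = 0.101). MYC, the growth-promoting transcription factor and a known oestrogen target, had a log2 change of −0.85 (adjusted p = 0.199, 0.0413 with the block). CCND1, which encodes cyclin D1, had one of 0.36 (adjusted p = 0.884), and E2F1 of −0.40 (adjusted p = 0.533). The 17 p53 targets gave an adjusted p of 0.689, although TP53I3 (log2 1.63) and PERP (1.40) rose (3 higher and 2 lower with the block). The call of PERP was lost without 3 of the 12 arrays in turn, while that of TP53I3 held. The 27 apoptosis regulators gave one of 0.544, with 0 members called over all probe sets or over the list alone and 1 lower with the block.

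The list of E2-induced genes of breast cancer cells rose, and its call held with an estimated correlation (adjusted p = 0.00134) as well as with the preset (adjusted p = 1.71e-15). Its median log2 change was 0.55 and 28 of 34 members were positive. The 6 members called over all probe sets were TFF1, SERPINA1, KRT13, HSPB8, GREB1 and NHERF1, the last named after its value was seen. There were 13 higher and 1 lower with the block, and 16 higher and 1 lower, MYC, when adjusted over the list alone. Luminal epithelial markers had a median of 0.34 over 19 genes (adjusted p = 0.000167; adjusted p = 0.107 with an estimated correlation). Of them 2 were called, CDH1 and ELF3, 4 when adjusted over the list alone and 5 with the block. In the 9 histone genes the median was 0.67 (adjusted p = 0.00251; adjusted p = 0.162 with an estimated correlation), with 1 called, H2AC6 (log2 1.19), 2 when adjusted over the list alone and 4 with the block. The 17 E2-repressed genes gave an adjusted p of 0.557, and the member that was called, CYP1A1, an enzyme that oxidises foreign compounds and estradiol, rose by 3.20 on the log2 scale (adjusted p = 0.0204), against the direction in the list's name. With the block 2 of its members were higher and 1 lower. The calls of ELF3, H2AC6 and CYP1A1 were lost without 9, 4 and 4 of the 12 arrays in turn.

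The remaining lists were not called in this comparison. The 23 genes of xenobiotic metabolism and oxidative stress had a median of −0.17 while the test's direction was upward (adjusted p = 0.0841), and 4 members rose: CYP1A1 and the metal-binding metallothioneins MT1F (log2 1.44), MT1H (1.37) and MT1X (1.13). When adjusted over the list alone 7 were higher and 2 lower, and 9 were higher and 2 lower with the block. Among 20 AP-1 and immediate early genes (adjusted p = 0.787) FOSL1 fell and ZFP36 rose, with 5 higher and 4 lower when adjusted over the list alone, and 3 higher and 4 lower with the block. The growth factor TGFA (log2 2.04, adjusted p = 0.00122) and IGFBP3, which binds insulin-like growth factors (1.83, adjusted p = 0.0337), rose in a list of 25 growth factors and receptor tyrosine kinases (adjusted p = 0.193; 3 higher and 2 lower with the block). In the 16 mesenchymal and basal markers (adjusted p = 0.728), SNAI1, a repressor of E-cadherin, rose by 3.08 on the log2 scale and FOSL1 fell. A single member rose in each of 4 lists: INHBB in the TGF-beta pathway (adjusted p = 0.544; 4 higher and 3 lower with the block), ISG20 in the interferon response (0.464; 2 higher and 4 lower with the block), CHAC1 in the unfolded protein and integrated stress response (0.728), and CYP1A1 as above. Of the 22 NF-kB and inflammatory genes (adjusted p = 0.544), 37 extracellular matrix genes (0.712), 13 heat shock genes (0.557), 21 cholesterol and fatty acid genes (0.159), 27 hypoxia and glycolysis genes (0.557), 22 ribosomal proteins (0.653) and 17 steroid receptors and cofactors (0.676), 0 were called by limma over all probe sets. With the block 3 NF-kB and inflammatory genes were higher and 1 lower, 1 extracellular matrix gene was higher and 2 lower, and 1 hypoxia and glycolysis gene was higher and 3 lower. The block also called 2 steroid receptors and cofactors and 1 cholesterol and fatty acid gene as higher. Of the members named in these lists, the calls of MT1X, CHAC1, ZFP36, ISG20 and IGFBP3 were lost without 11, 10, 9, 7 and 5 of the 12 arrays in turn. Those of CYP1A1 and MT1H were lost without 4 each and that of MT1F without 2. The calls of FOSL1, TGFA, SNAI1 and INHBB held whichever array was left out.

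The 19 luminal markers had a median intensity of 731.5 in Ad-ERα vehicle and 1216 in Ad-ERα E2 arrays, and the 16 mesenchymal and basal markers 3220 and 2110. The median log2 change of the mesenchymal and basal markers was −0.092, with 7 positive and 9 negative. Lists for other cell types were dim. The median intensity of the 9 measured leukocyte markers was 160.3 in Ad-ERα vehicle and 120.0 in Ad-ERα E2 arrays (list adjusted p = 0.378), and that of the 6 fibroblast markers 234.1 and 217.1 (adjusted p = 0.544). With 2 endothelial and 4 embryonic kidney packaging cell markers measured, these lists were too small to test; their medians were 148.8 and 152.6, and 106.6 and 109.7.

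**Figure D2:**
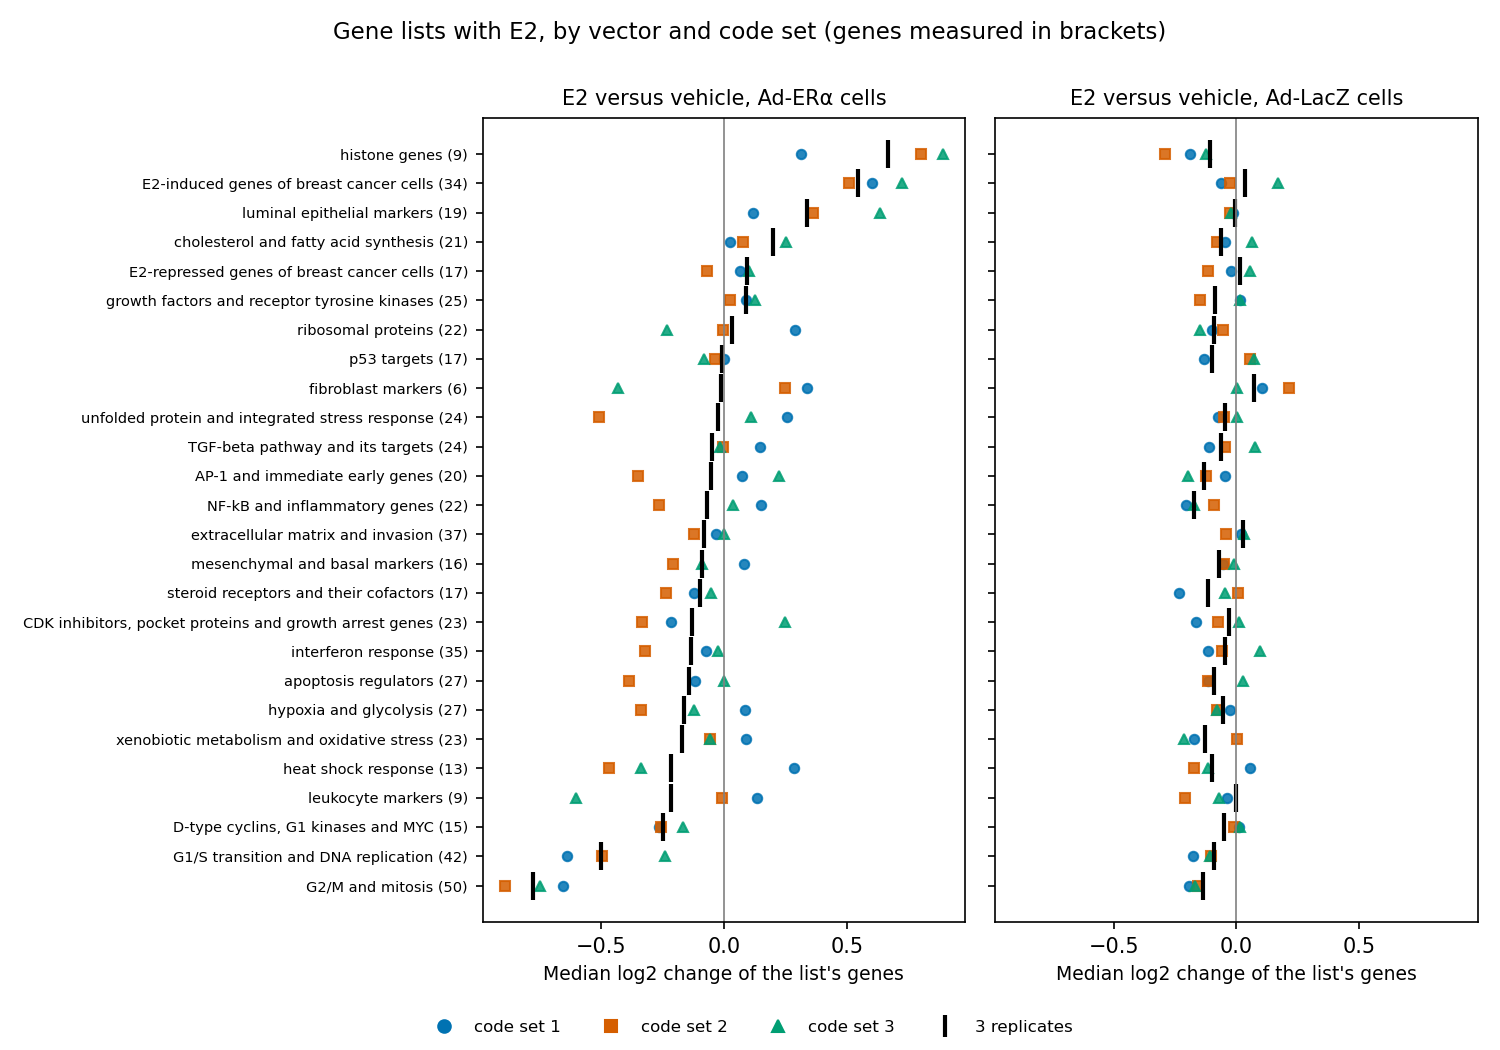
Median log2 change with E2 of the 26 tested gene lists in Ad-ERα (left) and Ad-LacZ cells (right), with a symbol per code set, a bar for the estimate over 3 replicates and the number of measured genes in brackets. The list for G2/M and mitosis lies at −0.78 in Ad-ERα cells and each code set lies below 0.

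Without the receptor, E2 changed no probe set and none of the fixed gene lists past the threshold. In Ad-LacZ cells limma called 0 probe sets, and 119 had an unadjusted p under 0.05 where 712 would be given by chance. With the block the count was also 0, with 318 at an unadjusted p under 0.05. The fit without it keeps the spread between code sets in its error, so 119 against 712 is no evidence against an effect. TFF1 read 187.3 ± 98.9 in vehicle and 191.9 ± 44.2 in E2 (SD, n = 3; log2 0.07), and GREB1 had a log2 change of 0.03. None of the 26 lists was called by limma's camera, the smallest adjusted p being 0.354. That value belongs to both cell cycle lists among others: 38 of 50 G2/M genes were negative with a median of −0.137 (unadjusted p = 0.0158), and 32 of 42 G1/S genes with a median of −0.09 (unadjusted p = 0.0436). The 147 probe sets that rose in Ad-ERα cells had a median log2 change of −0.07 in Ad-LacZ cells, where 57 of them (38.8%) were positive. Of the 14 that fell, 11 (78.6%) were negative in Ad-LacZ cells too, with a median of −0.099. Leaving out an array gave 2 called lists without replicate 1 and 3 without replicate 2 of the Ad-LacZ E2 arrays, and 2 without replicate 1 or replicate 3 of the Ad-LacZ vehicle arrays.

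The difference between the E2 effects in the 2 vectors was tested directly. Here 24 probe sets naming 18 genes were called, all with a larger effect in Ad-ERα cells. ALPP (log2 difference 5.69, adjusted p = 0.00233), TFF2 (5.37, adjusted p = 0.0276), CXCL14 (4.60, adjusted p = 0.00724), TFF1 (4.27, adjusted p = 0.000266), KRT13 (3.24, adjusted p = 0.0276), SERPINA1 (3.21, adjusted p = 0.000266), HSPB8, a small heat shock protein (2.55, adjusted p = 0.0446), and TGFA (2.17, adjusted p = 0.0276) were among them. Among these 8 named probe sets the calls of ALPP, TFF1 and SERPINA1 held whichever array was left out. The other 5 were lost without at least 1 array, with adjusted p up to 0.156. For the remaining calls, such as those of TMOD1 (log2 difference 4.42 and 3.10 in its probe sets) and SLCO2A1 (3.125), this was not examined. None of the 14 lower probe sets was called in this comparison, where 716 probe sets had an unadjusted p under 0.05 and chance would give 712. With the block 152 were called, 142 higher and 10 lower, and 1692 had an unadjusted p under 0.05. The fit without the block keeps the spread between code sets in its error, so 712 is not its exact chance level.

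By list, the E2-induced genes differed between the vectors with a median of 0.54 (adjusted p = 2.96e-13; adjusted p = 0.00238 with an estimated correlation). G2/M and mitosis genes differed by −0.63 (adjusted p = 2.26e-15; adjusted p = 0.339 with an estimated correlation), and genes of the G1/S transition by −0.44 (adjusted p = 0.000168; adjusted p = 0.871 with an estimated correlation). Histone genes differed by 0.69, positive in 9 of 9 (adjusted p = 0.000603), and luminal markers by 0.41 (adjusted p = 0.000755), each with adjusted p = 0.123 with an estimated correlation. The xenobiotic list differed by 0.17 (adjusted p = 0.0273; adjusted p = 0.904 with an estimated correlation). This call of the xenobiotic metabolism list was lost without replicate 2 (0.0602) or 3 (0.137) of the Ad-ERα E2 arrays and without replicate 1 of the Ad-ERα vehicle arrays (0.45). It was also lost without replicate 1 of the Ad-LacZ E2 arrays (0.347), replicates 2 (0.139) or 3 (0.144) of the Ad-LacZ vehicle arrays, or code set 1 (0.272). The count of 24 probe sets became 135 without replicate 1 of the Ad-ERα E2 arrays and 8 without replicate 2 or 3 of them. It was 13 and 14 without replicates 2 and 3 of the Ad-ERα vehicle arrays, and 9 and 10 without replicates 2 and 3 of the Ad-LacZ E2 arrays. The other counts were 14, 10 and 10 without replicates 1, 2 and 3 of the Ad-LacZ vehicle arrays, and 59, 3 and 0 without code sets 1, 2 and 3 (the 0 with 402 at an unadjusted p under 0.05 in limma's fit).

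**Figure D3:**
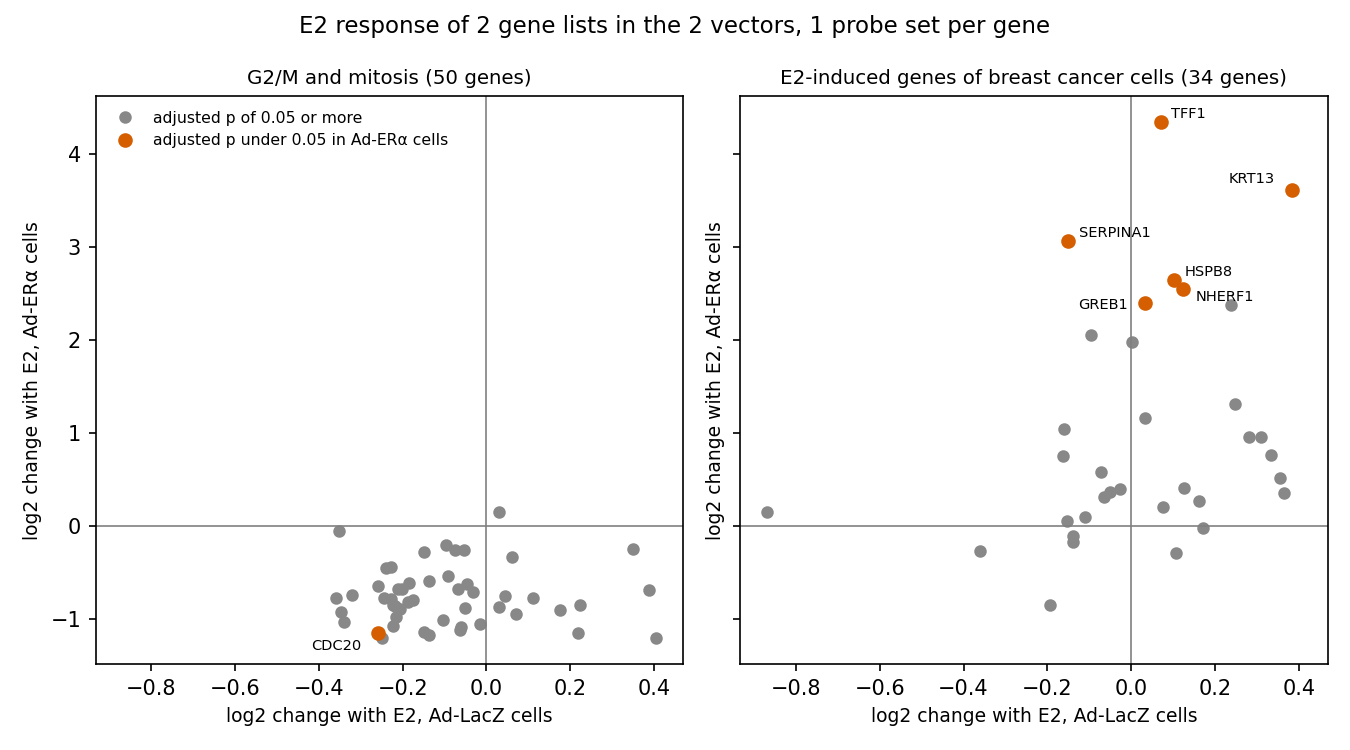
Log2 change with E2 of each measured gene in Ad-LacZ cells (horizontal) and in Ad-ERα cells (vertical), for G2/M and mitosis (left, 50 genes) and E2-induced genes (right, 34 genes), 1 probe set per gene. Coloured and named genes had an adjusted p under 0.05 in Ad-ERα cells, and 49 of 50 G2/M genes lie below 0 on the vertical axis.

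The receptor without added hormone changed little besides its own transcript. In vehicle, 6 probe sets differed between Ad-ERα and Ad-LacZ cells, the 5 of ESR1 and that of CRYAB, a small heat shock protein, which rose from 57.8 to 286.0 ± 36.6 (SD, n = 3; log2 2.15, SE 0.29, adjusted p = 0.00977). The call of CRYAB was lost without replicate 2 (adjusted p = 0.112) or 3 (0.0723) of the Ad-ERα and replicate 2 (0.0614) or 3 (0.0669) of the Ad-LacZ vehicle arrays. The heat shock response list was higher, with 13 of 13 members positive and a median of 0.29 (adjusted p = 5.11e-11; adjusted p = 0.677 with an estimated correlation). In it 1 member passed over all probe sets and 3 when adjusted over the list alone, CRYAB, HSPA6 (log2 3.04) and DNAJB1 (0.85). Genes of the G1/S transition were lower by a median of −0.08 (adjusted p = 0.00222; adjusted p = 0.992 with an estimated correlation). This call was lost without replicate 1 (0.39) or 2 (0.247) of the Ad-LacZ vehicle arrays, and its direction turned without replicate 3 of the Ad-ERα vehicle arrays (0.977). It was also lost with array weights (0.29) and without code set 1 (0.0778) or 3 (0.103). The number of called lists, 2, became 1 without replicate 1 of the Ad-LacZ and 6 without replicate 1 of the Ad-ERα vehicle arrays. The G2/M genes had a median of −0.07 (adjusted p = 0.184), and 173 probe sets had an unadjusted p under 0.05 where chance would give 712. With the block 458 probe sets did. Here too 712 is not the exact chance level of the fit without the block.

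The last comparison set cells with and without the receptor against each other in E2. ALPP (log2 5.57), CXCL14 (5.01), TFF2 (4.89), TFF1 (4.39), GREB1 (2.78) and CDH1 (4.24) were higher in Ad-ERα cells, each with an adjusted p of 0.00128 or less, and CRYAB was higher by 1.73 (adjusted p = 0.00754). FOSL1 (−1.34, adjusted p = 0.00621), FAM216A (−1.28), GSDMD (−1.35), BACH1 (−1.26) and ASCL3 (−1.64) were lower. The calls of these 5 were lost without replicate 3 of the Ad-ERα E2 arrays (adjusted p = 0.054 for FOSL1, 0.0631 for FAM216A, 0.14 for GSDMD, 0.149 for BACH1 and 0.14 for ASCL3). All but that of FOSL1 were also lost without replicate 2 of the Ad-ERα E2 arrays (0.0624, 0.101, 0.193 and 0.0996, in the same order) and without replicate 3 of the Ad-LacZ E2 arrays (0.051, 0.168, 0.152 and 0.13). In all, the calls of GSDMD and BACH1 were lost without 9, and that of ASCL3 without 8, of the 12 arrays in turn. CDKN1A was higher by 1.34 (adjusted p = 0.0386), a call lost without 9 of the 12 arrays in turn, with the highest adjusted p = 0.226 without replicate 3 of the Ad-ERα E2 arrays. Over all probe sets limma called 202 probe sets, 191 higher and 11 lower, and 927 with the block, 677 higher and 250 lower. The count was 385, 79 and 72 without replicates 1, 2 and 3 of the Ad-ERα E2 arrays. It was 111, 103 and 129 without replicates 1, 2 and 3 of the Ad-LacZ E2 arrays, and 40 and 23 without code sets 2 and 3.

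Of the lists in this comparison, G2/M and mitosis genes had a median of −0.75 (adjusted p = 7.32e-22; adjusted p = 0.17 with an estimated correlation), with 1 member lower over all probe sets, 22 when adjusted over the list alone and 29 with the block. G1/S genes had a median of −0.47 (adjusted p = 4.45e-10; adjusted p = 0.377 with an estimated correlation). E2-induced genes had a median of 0.51 (adjusted p = 1.51e-11; adjusted p = 0.00392 with an estimated correlation) and luminal markers, which include ESR1 itself, one of 0.44 (adjusted p = 1.05e-05; adjusted p = 0.0534 with an estimated correlation). Histone genes (0.59, adjusted p = 0.00181; adjusted p = 0.17 with an estimated correlation), heat shock genes (0.34, adjusted p = 0.00184; adjusted p = 0.682 with an estimated correlation) and xenobiotic genes (0.24, adjusted p = 0.00319; adjusted p = 0.738 with an estimated correlation) were higher. The xenobiotic call was lost without replicate 1 of the Ad-LacZ E2 arrays (adjusted p = 0.101). With the block, ribosomal proteins were called as well, 22 of 22 positive with a median of 0.19 (adjusted p = 0.00578). That call was lost with the block and an estimated correlation (adjusted p = 0.738).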

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

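The tests of code sets and of the vector without hormone for the G2/M list, both tests with the code sets as a block for the direction of the calls, and both tests for the heat shock genes were chosen after the result was seen. The scaling alternative without a shift was added after seeing the data.

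The effect of E2 differed between Ad-ERα and Ad-LacZ cells, by limma's interaction test, for ALPP (log2 difference 5.69), TFF2 (5.37), CXCL14 (4.60), TFF1 (4.27), KRT13 (3.24), SERPINA1 (3.21), HSPB8 (2.55) and TGFA (2.17). By the list test it differed for E2-induced genes (median 0.54; adjusted p = 0.00238 with an estimated correlation), G1/S genes (−0.44; adjusted p = 0.871 with an estimated correlation), G2/M genes (−0.63; adjusted p = 0.339 with an estimated correlation), histone genes (0.69; adjusted p = 0.123 with an estimated correlation), luminal markers (0.41; adjusted p = 0.123 with an estimated correlation) and xenobiotic genes (0.17; adjusted p = 0.904 with an estimated correlation). Outside the comparisons, the control probe set for 18S ribosomal RNA read 10148 in Ad-ERα vehicle replicate 2 and 10703 in Ad-ERα E2 replicate 2, above the 306.3 to 4512 of the Ad-LacZ vehicle arrays.

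Other groupings of the same arrays were refitted. For E2 against vehicle in Ad-ERα cells the real grouping called 161 probe sets and the highest other grouping 0, counting 1 of 10 as large. For the vectors in E2 it called 202 against 0 (1 of 10), for the vectors in vehicle 6 against 0 (1 of 10), and for E2 in Ad-LacZ cells 0 against 0 (10 of 10). For lists the real groupings called 5 against at most 8 in another (6 of 10 as large), 7 against 6 (1 of 10), 2 against 8 (8 of 10) and 0 against 8 (10 of 10), in the same order. With 10 splits no share under 0.05 can be reached, and each other split still holds part of any real difference between the groups. Among the 3 other splits that part every code set, as the real one does, the highest numbers of probe sets were 0, and of lists 6, 4, 2 and 0 in that order, so the 8 lists came from splits that keep arrays of a code set together. For the interaction 10 of 100 drawn splits called as many as the 24 probe sets, the highest 63, and 32 of 100 called as many as the 6 lists, the highest 10, so chance cannot be excluded for either count. For the probe sets this rests on splits that hold the E2 effect themselves: 8 of those 10, the real one included, kept the Ad-ERα arrays in their real groups, as 14 of the 100 did. Of the 86 that did not, 2 called as many (highest 55). Among the 19 others that part every code set the highest was 21, in a split that kept the Ad-ERα arrays in their real groups. Those of the 19 that did not keep them called 0. With the block 8 of 100 gave as many as the 152 calls, the highest 395. All 8 kept the Ad-ERα arrays in their real groups, and the highest of the 86 splits that did not keep them was 1.

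The G2/M and mitosis list was lower with E2 in Ad-ERα cells. Array scaling is argued against by a median of −0.75, the value closest to 0 under the deposited scaling and quantile normalization. A single code set is argued against by a median of −0.66 in the set closest to 0, and the vector without hormone by a median of −0.073 in vehicle. The argument against array scaling was made for the G2/M list alone. That against a single code set does not carry over to the G1/S list, whose code set medians were −0.639, −0.497 and −0.242. Between the vectors in vehicle the G1/S list had a median of −0.08. It was itself called there (camera adjusted p = 0.00222), though not with an estimated correlation (adjusted p = 0.992). The fall of the G2/M list may be a response to hormone and receptor together, but its median in Ad-LacZ cells was −0.137. The list was also called in 7 of the 9 other splits of the 6 arrays, where its largest other median was 0.60 in size (0.32 among splits that part every code set). Each of these splits divides the E2 arrays unevenly and so holds part of the E2 difference, so they cannot decide this. The correlation estimated between the genes of this list is 0.388, above the preset 0.01 (adjusted p = 0.162 with an estimated correlation, 0.0403 with the block as well), and a slower or differently timed culture was not tested.

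With E2 in Ad-ERα cells 147 probe sets were higher and 14 lower. The spread between code sets may account for part of this imbalance, since with the code sets as a block 40.4% of the calls were lower. Dim probe sets that can only rise do not account for the whole of it, since among 89 calls bright in Ad-ERα vehicle arrays 86.5% were higher. With the block 51.1% of 634 bright calls were higher, so there an excess of rises is left among the dim probe sets. The limit on blocked counts applies here: of 100 simulations without added change the block made calls in 4, and 865 of them in 1. In the other splits of the same arrays the highest blocked count was 0, but each of those splits holds part of the E2 difference.

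Heat shock genes were higher in Ad-ERα vehicle arrays than in Ad-LacZ vehicle arrays. A single code set is argued against by the lowest of the 3 medians, 0.25. A chance difference in the vehicle arrays stays open. The list was higher in the 6 E2 arrays too (adjusted p = 0.00184), but these come from the same code sets and are no independent check. The list's call is lost with an estimated correlation in both (adjusted p = 0.677 in vehicle and 0.682 in E2). Ad-LacZ cells carry a vector with an introduced gene too, so introduced protein in general need not differ between the groups. A candidate explanation is a response of the cells to the introduced receptor in particular, which these arrays did not test. A difference between the virus preparations stays open as well.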

How the results depend on the processing

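The deposited scaling without a shift, and the block with an estimated correlation for the lists, were chosen after seeing the data. The count of 5 ESR1 probe sets and the 0 calls for E2 in Ad-LacZ cells (limma; 119 at an unadjusted p under 0.05) held under every alternative run, and 1 called result reversed: the G1/S list between the vectors in vehicle, whose adjusted p ran from 2.5e-07 to 0.977 over left-out arrays, the 0.977 with turned sign without replicate 3 of the Ad-ERα vehicle arrays. Of 589 named gene results, 82 were called; over 16827 values under alternatives, 16138 stayed on the same side of the threshold, 453 lost and 236 gained a call, 92 of the gains with the replicate block. The replicate block took away the call of no named gene. It moved the counts for E2 in Ad-ERα cells from 161 to 845, for the interaction from 24 to 152, for the vectors in vehicle from 6 to 8 and for the vectors in E2 from 202 to 927. It added the ribosomal protein list in that last comparison (adjusted p = 0.738 with the block and an estimated correlation). Apart from the named genes that gained a call, it changed no other call of a named gene or fixed list; for gene families its values stand with them. For E2 in Ad-ERα cells fits to 2 groups alone called 101, array weights 316, the code prefix as a block 314, and leaving out code sets or arrays between 8 and 347 (56 to 347 for single arrays). For the interaction quantile normalization gave 38, the 4-fold added value 41, array weights 61, the prefix 59, and left-out sets or arrays 0 to 135 (8 to 135 for single arrays). For the vectors in E2 the counts were 120 with 2 groups alone, 378 with weights, 393 with the prefix, and 23 to 385 (72 to 385 for single arrays). For the vectors in vehicle 1 probe set per gene gave 2 in place of 6, because ESR1 has several probe sets, and left-out arrays 5 to 6. The cause of the other moves was not tested, beyond fewer arrays in a fit.

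An estimated correlation left 1, 0, 1, 0 and 1 lists called where the preset called 5, 0, 6, 2 and 7 (E2 in Ad-ERα cells, E2 in Ad-LacZ cells, interaction, vectors in vehicle, vectors in E2), the block with it 2, 0, 1, 0 and 2, and fry 4, 0, 1, 0 and 4. For E2 in Ad-ERα cells the calls lost with an estimated correlation were G1/S (adjusted p = 0.606, 0.11 with the block, 0.222 with fry), G2/M (0.162), histone genes (0.162, 0.0733 with the block) and luminal markers (0.107, 0.19 with the block). The probe set with the largest SD gave 4 lists for the vectors in vehicle. Array weights gave 2 for E2 in Ad-LacZ cells and 1 for the vectors in vehicle. Without code set 2 the vectors in E2 had 11. Left-out arrays gave 5 to 7, 0 to 3, 5 to 7, 1 to 6 and 6 to 8 lists. Over all left-out arrays and sets the adjusted p of the 5 lists called for E2 in Ad-ERα cells ranged from 7.21e-27 to 7.05e-14 (G2/M), 1.31e-16 to 8.89e-11 (E2-induced), 1.77e-12 to 0.00425 (G1/S), 0.000192 to 0.00618 (luminal) and 0.00125 to 0.0371 (histone). The other spread models were not run for lists. The camera tests used its default spread model, which has no intensity trend, unlike the fit of the genes. Probe sets near the added value of 15.9 have folds that depend on it.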

Other observations

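The gene families below were chosen after seeing the data, by grouping all tested genes by the root of their symbol into 285 families of at least 5 genes. They were tested for E2 in each vector and for the vectors in vehicle. Metallothioneins, small proteins that bind zinc and copper, were positive with E2 in Ad-ERα cells in 8 of 8 members, of which 3 were called (7 with the replicate block), with a median log2 change of 1.04 (1.00 with quantile normalization, 1.04 with the deposited scaling; camera adjusted p = 4.17e-08 over all families). With an estimated correlation the adjusted p = 0.998. MT1F rose from a mean intensity of 2020 to 5590, and MT1X from 6860 to 15100. MT2A read 13600 and 23900 (log2 0.82, adjusted p = 0.244, 0.00317 with the block), and MT3 read 198 and 212 (log2 0.124, adjusted p = 0.965). In Ad-LacZ cells the family's median was −0.20, and the difference between the vectors had a median of 1.21 (adjusted p = 3.92e-10; adjusted p = 0.992 with an estimated correlation). Many of these probe sets can bind transcripts of several metallothionein genes, so the members are not independent.

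Cystatins, secreted inhibitors of cysteine proteases, were positive in 7 of 8 members. Of the 8 members 1 was called, and 6 with the block, among them CST7, whose change was negative. The family's median was 1.33 (1.21 with quantile normalization, 1.33 with the deposited scaling, camera adjusted p = 0.0226, and adjusted p = 0.998 with an estimated correlation). CST5 rose by 2.90 on the log2 scale (adjusted p = 0.00679), while CST1 had a log2 change of 2.50 (adjusted p = 0.327, 0.00361 with the block) and CST4 of 1.88 (adjusted p = 0.335, 0.00339 with the block). CST7 had one of −0.79 (adjusted p = 0.527, 0.0486 with the block). The test of the difference between the vectors gave an adjusted p of 0.183 for the family (0.0299 with the block, but 0.994 with the block and an estimated correlation). Pregnancy-specific glycoproteins were positive in 6 of 6 members with a median of 0.80 under each of the 3 scalings (adjusted p = 0.00272, and adjusted p = 0.998 with an estimated correlation). None of them was called over all probe sets. As with the metallothioneins, probe sets of this family can bind transcripts of several members, so the members are not independent. In Ad-ERα vehicle arrays PSG7, PSG1 and PSG5 read 70.2, 88.5 and 103, below the filter level of 111. PSG4 (log2 0.81, adjusted p = 0.0807) and PSG9 (log2 0.82, adjusted p = 0.129) had an adjusted p of 0.016 and 0.0353 with the block. The difference between the vectors had an adjusted p of 0.00756 for this family (0.0542 with the block, 0.992 with an estimated correlation).

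The screen called 3 further families, with 0 members called in each. In Ad-LacZ cells with E2 the TMPRSS proteases were positive in 6 of 6 members, with a median of 0.352 (0.347 with quantile normalization, 0.397 with the deposited scaling; adjusted p = 0.0391, 0.0771 with the block, 0.996 with an estimated correlation). Between the vectors in vehicle, HSPA heat shock proteins were positive in 8 of 8 members, with a median of 0.237 (0.204 and 0.192 under those scalings; adjusted p = 0.00119, 0.998 with an estimated correlation). Carbonic anhydrases were positive in 2 of 7, with a median of −0.25 (−0.249 and −0.295; adjusted p = 0.023, 0.305 with the block, 0.998 with an estimated correlation). With no block, the number of splits that gave as many called lists as the real one was 6 of 10 for E2 in Ad-ERα cells, 10 of 10 for E2 in Ad-LacZ cells and 8 of 10 for the vectors in vehicle, so the preset test of families carries the same limit.

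The signal of the 18S ribosomal RNA control probe set followed the code sets more than the groups: it ranged from 93.2 to 306.3 in code set 3, from 1098 to 4080 in code set 1 and from 2009 to 10703 in code set 2.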
